A study of Homo sapiens with 6 samples.

How the data were processed

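Total RNA from 3 samples of parental LC-2/ad cells and 3 samples of the dovitinib-resistant derivative was purified on RNeasy columns, amplified with a TargetAmp-Nano kit and labelled with biotin for an Illumina expression bead chip, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which call the parental cells control. The authors deposited a table of 47323 probes with, for each array, a probe intensity on a linear scale and a detection p-value. The deposited intensity values are not normalized, per the file headers, and no background subtraction is visible in them. The deposited detection p-value ranks a probe's signal among 770 steps of negative controls, as read from the values, and software for scanning or export is not given in the sources used here. Median intensities were 130, 127 and 135 on parental and 144, 140 and 130 on resistant replicates 1, 2 and 3, and no 2 arrays held identical values.

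The deposited series matrix holds the same intensity values: each of its 47323 sets of 6 values was found in the non-normalized table, and its columns tie the table's columns to the samples. Its scale is linear, it is neither centred nor normalized, and its column medians equal those above. Only 1 probe ID agreed between both tables. Probe names of the non-normalized table were used, because pairs of probes of the same gene correlated at 0.524 there against 0.043 in the series matrix, and probes of EEF1A1, ACTB and GAPDH had a median log2 signal of 15.5 there against 7.68. The series matrix alternative therefore used its values without normalization under the names of the non-normalized table.

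Gene symbols came from the platform annotation: 30113 probes had 1 symbol, 8 had several and 17202 had none here, and no gene was named from a probe with several. No symbol needed updating through the RefSeq gene table of assembly GRCh38.p14, which was otherwise used only for the chromosome of a gene and for which genes neighbour each other, since no build is named in the files. Of 1428 entries in the gene lists, 1422 were matched to a gene, and CCDC6 was not analysed here for lack of a named probe.

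Signals were background-corrected, quantile-normalized and put on a log2 scale with neqc of limma 3.58.1 (offset 16, background estimated from the detection p-values) in R 4.3.3 with the data.table package, version 1.17.8. Probes entered the test when the detection p was under 0.05 on at least 3 arrays, which left 20951 probes, 15806 of them with 1 symbol. Differences between resistant and parental cells were fitted with lmFit and eBayes of limma on all 6 arrays with the group as the only term, and called at a Benjamini-Hochberg adjusted p under 0.05. The fold and log2 differences are relative to a quantile normalization, so a change shared by most genes would be removed. For gene-level results each gene was represented by its tested probe of highest mean signal, which gave 11846 genes.

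A probe detected on all 3 arrays of 1 group and on none of the other has only a bound on its fold. For it the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest detected normalized signal and the probe's own signal, and the result is written as at least N-fold. Its adjusted p comes from the fit of the measured signals.

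A set of 42 gene lists was fixed from general knowledge: dovitinib target kinases, other receptor tyrosine kinases, growth factor ligands, Src family kinases and partners, focal adhesion and integrins, extracellular matrix, matrix proteases, MAPK output, PI3K and FOXO, epithelial, mesenchymal, TGF-beta, YAP and TAZ, lung lineage, mucins, squamous, neuroendocrine, leukocyte, endothelial and stromal, both cell cycle lists, p53, interferon, antigen presentation, NF-kB, complement, integrated stress, ER chaperones, heat shock, cholesterol, fatty acid, lysosome and autophagy, NRF2, AHR, xenobiotic metabolism, ABC transporters, hypoxia, oxidative phosphorylation, BCL2 family, Wnt, Notch and stem-like markers. The lists share genes: 9 of the 20 tested mesenchymal markers, 6 of the 28 YAP and TAZ targets, 4 of the 16 lung lineage genes and 1 of the 50 G2 and M genes stand in another list too, as do 4 of the 7 endothelial and stromal and 1 of the 10 leukocyte markers. The 41 lists with at least 5 tested genes were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists. With an estimated correlation for each list camera made 0 calls (5 lists at an unadjusted p under 0.05). The estimate was 0.248 for mucins. For the other called lists it lay below the preset 0.01: -0.0085 for G2 and M, -0.024 for integrated stress, -0.013 for mesenchymal, -0.0093 for YAP and TAZ and -0.0075 for lung lineage genes. A higher correlation was therefore not what ended those calls.

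Genes are named in the text by a rule. It takes the 12 largest increases and 12 largest decreases among genes past the threshold, detected on all 6 arrays and without overlap between the groups, the 5 largest bounds in each direction, every dovitinib target kinase and SRC, and up to 4 members past the threshold with the largest difference in each called list and in the Src and focal adhesion lists. Symbols starting with LOC and placeholder symbols were passed over. The groups, the test, the lists, the rule and the alternatives were fixed before the data were examined, except where the closing observations say otherwise.

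The fit and the list test were tried on simulated signals drawn on the normalized scale, so normalization was not tested. In them 200 of the 20951 probes were changed and 10 sets were drawn per fold. Recovered were 0% of probes changed 1.2-fold, 42.9% at 1.5-fold, 76.6% at 2-fold and 97.4% at 4-fold, with false calls making up 0%, 6.23%, 4.55% and 5.71% of calls. In the real comparison 8133 probes were called, which loosens the cutoff on the unadjusted p. The recovered shares therefore do not give the recovery of the real comparison. With no change limma made 0 calls, and 1088 probes had an unadjusted p under 0.05. Over 11846 genes drawn independently of each other, 29 of 29 lists of at least 20 genes were recovered with camera when shifted by 0.5 log2, and 0 of 1189 tests of unshifted lists were called (32 at an unadjusted p under 0.05).

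Alternatives covered the background correction (none, or normexp with an offset of 50), the normalization (median scaling, cyclic loess, or the series matrix values), the filter on dim probes, the variance model, array weights, the replicate number as a block, an adjusted p under 0.01, the mean of a gene's probes, an estimated correlation, fry in place of camera, and leaving out each array. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Probes without a gene symbol were tested but not named, and genes of chromosome Y were left out of the values given per chromosome.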

Results

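Gene expression was measured in LC-2/ad, a human lung adenocarcinoma cell line that carries a CCDC6-RET fusion gene, and in a derivative of it that had become resistant to dovitinib. Dovitinib (TKI258) is a small molecule that inhibits several receptor tyrosine kinases, among them RET and the receptors for FGF, VEGF and PDGF. The resistant cells were obtained by growing the parental line in rising amounts of the drug, and their IC50 was above 3 µmol/L. The labels do not say whether the drug was present when RNA was taken. Labelled cRNA from 3 parental and 3 resistant samples was hybridised to Illumina expression bead chips of 47323 probes. Between 42.4% and 43.9% of the probes were detected on each array, and the number of arrays limits the precision of every value. The labels do not say that the 3 samples of a group were grown apart, so the p-values measure the spread between these samples, which may be technical. Signals correlated with r of 0.993 to 0.996 between arrays of a group and 0.970 to 0.973 between arrays of different groups.

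The comparison of resistant with parental cells asks which genes differ in cells that have acquired resistance. PVT1, a long non-coding RNA gene next to MYC, was 31.1-fold higher in resistant cells (4.96 ± 0.11 log2, SE, n = 3 per group). MAL, a membrane proteolipid of epithelial cells, was seen only on resistant arrays and was at least 56.3-fold higher, and OLFM4, a secreted glycoprotein of epithelia, was at least 32.5-fold higher. LCP1, an actin-bundling protein, was 28.5-fold lower (-4.83 ± 0.10 log2, SE, n = 3 per group). NKX2-1, the transcription factor of the lung epithelial lineage, was detected on all 3 parental arrays and on none of the resistant ones, at least 18.0-fold lower. Adjusted p values from limma were 1.16e-06 for PVT1, 1.01e-06 for LCP1 and 4.36e-07 for MAL, OLFM4 and NKX2-1, and in each of these genes all 3 resistant arrays lay on the same side of all 3 parental ones. For PVT1 and LCP1 the naming rule requires such separation. For MAL, OLFM4 and NKX2-1 it asks for detection in 1 group alone and a large bound, which all but forces it.

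Among genes detected on all 6 arrays, the 12 largest increases ran from PVT1 to SFRP1, a secreted antagonist of Wnt signalling, at 7.42-fold. HSPB8, a small heat shock protein, rose 15.7-fold (3.98 ± 0.06 log2), SDCBP2 13.9-fold, MAP1LC3A, a protein of the autophagosome membrane, 12.4-fold, and CLTRN by 3.59 log2. TNFRSF11B, the decoy receptor osteoprotegerin, rose 11.9-fold, the uroplakin gene UPK2 by 3.33 log2, KISS1, which encodes kisspeptin, 9.45-fold, and the carbonic anhydrase gene CA2 8.50-fold. EEF1A2, a translation elongation factor, rose 8.40-fold and the serine protease gene KLK5 7.85-fold. The limma adjusted p of these 12 genes was at most 2.37e-05, and each was higher in 3 of 3 resistant samples, which the naming rule requires. SDCBP2, MAP1LC3A and EEF1A2 lie on chromosome 20, where 250 of 328 tested genes rose. Both other probes of SDCBP2 were detected on resistant arrays alone and gave smaller bounds, at least 4.27-fold and 2.48-fold higher.

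The 12 largest decreases among genes detected on all arrays ran from LCP1 to NMU, the gene of the peptide neuromedin U, at 7.77-fold lower. EVA1A was 15.8-fold lower (-3.98 ± 0.11 log2), MAGEA6, a cancer-testis antigen, and NIBAN1 were each 13.8-fold lower, and MSLN, the cell-surface protein mesothelin, was 11.7-fold lower. PABPC4L was 11.3-fold lower, VCAN, the matrix proteoglycan versican, 10.4-fold, DNAJC12, a J-domain co-chaperone, 9.87-fold, and WASHC5, a subunit of the endosomal WASH complex, 9.55-fold. S100A4, a calcium-binding protein, was 8.29-fold lower and ABCA1, a cholesterol efflux transporter, 7.80-fold. The limma adjusted p of these 12 genes was at most 1.31e-05, and each was lower in 3 of 3 resistant samples, which the naming rule requires. MAGEA6 has near-identical family members whose RNA its probes may also bind, so its value is uncertain, and its 2 other probes, seen on parental arrays alone, gave at least 7.94-fold and 2.47-fold lower. Other probes seen on parental arrays alone were at least 9.50-fold and 6.62-fold lower for EVA1A and at least 14.2-fold, 8.15-fold and 2.63-fold lower for DNAJC12, and the other probe of S100A4 was 4.67-fold lower.

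Genes detected in 1 group alone have only a bound on their fold. Besides MAL and OLFM4, OLR1, a receptor for oxidised LDL, was at least 20.6-fold higher in resistant cells, the glucuronosyltransferase gene UGT1A6 at least 8.51-fold and LRRN2 at least 6.18-fold. UGT1A6 shares sequence with its neighbours in the UGT1A cluster and is uncertain for that reason. Besides NKX2-1, the transporter gene SLC16A9 was at least 14.6-fold lower, CEACAM6, a cell adhesion molecule, at least 12.8-fold, LUM, the proteoglycan lumican, at least 11.1-fold and SFTA3, a gene beside NKX2-1, at least 9.51-fold. The limma adjusted p of these 10 genes was at most 1.34e-05. The bounds hold for the brightest probe and for this background correction: without correction they were at least 20.7-fold for MAL, 12.2-fold for OLFM4, 7.99-fold for OLR1 and 7.15-fold for NKX2-1, and between 2.87-fold and 5.93-fold for the other 6. Other probes gave at least 14.99-fold for MAL, 9.54-fold for NKX2-1, 10.1-fold for SFTA3, and 7.68-fold and 2.27-fold for UGT1A6. In all, 106 genes passed the test and were detected on every resistant array and no parental one, and 166 passed with the reverse.

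**Figure D1:**
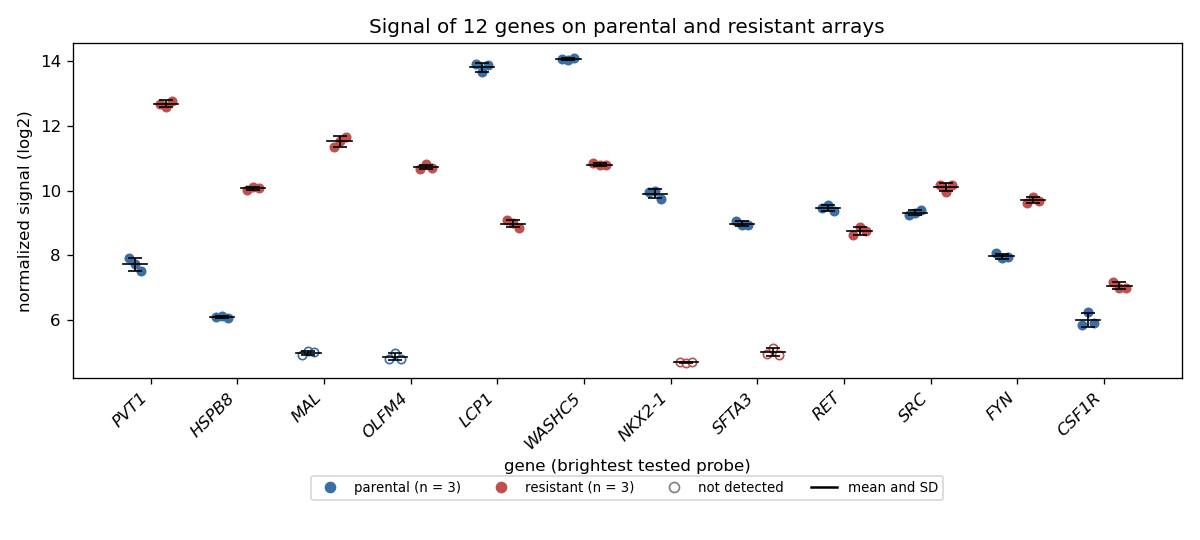
Normalized log2 signal of 12 genes on each array, as points for parental (n = 3) and resistant (n = 3) samples with the mean and SD of each group, and open points where the probe was not detected. PVT1 lay 4.96 log2 higher in resistant cells, and NKX2-1 was detected on parental arrays alone.

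Over all 20951 tested probes, limma called 4161 higher and 3972 lower in resistant cells, or 38.8% together. Of these, 580 were at least 2-fold higher and 583 at least 2-fold lower. Over 11846 genes, each by its brightest probe, 2744 rose and 2584 fell. Of the called probes 51.2% were higher, against 61.1% when arrays were scaled to 1 median and 72.4% in the deposited series matrix values without any normalization, where the median of all tested probes lay 0.11 log2 above 0. At least 2-fold changes fell to 269 higher and 299 lower without background correction, where 30 of 65 named genes had a fold over 1.5 times smaller, among them HSPB8 at 2.83 log2, MAP1LC3A at 2.37, EVA1A at -2.93 and MAGEA6 at -2.54. Of 3167 genes with several tested probes, 28 had probes called in opposite directions.

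Of the kinases that dovitinib inhibits, 4 were measurable. RET, the kinase of this line's fusion gene, fell by 0.72 log2 (SE 0.09, n = 3 per group, limma adjusted p = 0.00105), and of its 2 other tested probes 1 gave -0.56 (limma adjusted p = 0.00494) and 1 was detected on parental arrays alone, at least 1.43-fold lower (limma adjusted p = 0.0228). FGFR4 fell by 0.50 log2 (SE 0.08, limma adjusted p = 0.00346) and 2 other FGFR4 probes were not detected. CSF1R, the receptor for colony-stimulating factor, rose by 1.06 log2 (SE 0.12, limma adjusted p = 0.000881). FGFR3 rose by 0.36 log2 (SE 0.10, limma adjusted p = 0.0347), while its other probe gave 0.10 (limma adjusted p = 0.700). Adjusted over the list alone, the same counts of 2 rising and 2 falling kinases were obtained. FGFR1, FGFR2, FLT1, FLT3, FLT4, KDR and PDGFRB were detected on no array, KIT was detected on 1 parental array and PDGFRA on 2 resistant arrays, and CCDC6 was not analysed here. The FGFR4 call ended with the series matrix values (-0.22 log2, limma adjusted p = 0.128). The FGFR3 call ended without any 1 of 5 arrays, namely the 3 parental ones and resistant replicates 2 and 3 (limma adjusted p = 0.0600 to 0.100), with no filter on dim probes (0.0645) and with the mean of both probes (0.0791).

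In the list of Src family kinases and their partners, which act downstream of receptor kinases and integrins, 6 of 24 tested genes rose, 1 fell and 17 did not pass, and the counts adjusted over the list alone were the same, 6 and 1. FYN rose by 1.73 log2 (SE 0.08), the phosphatase gene PTPN1 by 1.05 and SRC by 0.79 (SE 0.09, limma adjusted p = 0.000668), and the Src-regulating adaptor PAG1 was at least 1.42-fold higher. SRC was read by 1 probe, since its 2 other probes were not detected. SRC and PTPN1 lie on chromosome 20, where the median gene was 0.62 log2 higher, and FYN on chromosome 6, where the median was 0.10. As a whole the list did not pass limma's camera (adjusted p = 0.669), with a median of -0.0017 log2 (0.13 under median scaling), a mean of 0.17 and a camera direction upward.

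Among focal adhesion and integrin genes 9 of 36 rose, 9 fell and 18 did not pass, or 9 and 10 adjusted over the list alone. MYL9, a myosin light chain, was at least 4.53-fold higher (at least 2.06-fold on its other probe, and 2.28-fold without background correction) and lies on chromosome 20, the actin crosslinker gene ACTN1 rose by 0.86 log2 (SE 0.07), and the integrin gene ITGB2 fell by 1.11 (SE 0.08). The kinase gene MYLK rose by 0.94 (SE 0.14) on its brightest probe and read 0.04 on its other one (limma adjusted p = 0.886). The list did not pass camera (adjusted p = 0.954), and its median of -0.041 log2 (0.0057 under median scaling) and downward test stood against a mean of 0.06.

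Of 41 lists tested with limma's camera, 6 passed. The largest number of changed genes was in the list of G2 and M phase genes, where 27 of 50 fell, 3 rose and 20 did not pass, or 32 falling and 4 rising adjusted over the list alone. The mitotic cyclin genes CCNB2 and CCNB1 changed by -1.06 (SE 0.07) and -0.91 log2 (SE 0.10), and the kinesin gene KIF20A by -0.99. The spindle protein gene HMMR went from a mean log2 signal of 13.32 to 12.31. The list median was -0.31 log2 (camera adjusted p = 5.85e-05, but adjusted p = 0.171 with an estimated correlation), and -0.14 in the series matrix values. G1/S and S phase genes went the other way without passing camera, with 15 of 41 rising, 6 falling, a median of 0.19 log2 and an adjusted p of 0.0950, or 17 rising and 7 falling adjusted over the list alone. Whether the 2 cell cycle lists differ was not tested.

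In the list of integrated stress response and amino acid genes 14 of 29 fell, 4 rose and 11 did not pass, or 16 falling and 4 rising adjusted over the list alone. DDIT4, an inhibitor of mTORC1 signalling, fell by 2.15 log2 (SE 0.15), the cystathionine lyase gene CTH fell by 1.91 (SE 0.08), PHGDH, which starts serine synthesis, fell by 1.37 and the amino acid transporter gene SLC7A5 fell by 1.31. The median was -0.27 log2 (camera adjusted p = 0.00436, but adjusted p = 0.245 with an estimated correlation). It shrank to -0.16 under median scaling and to -0.060 in the series matrix values, where camera still called the list.

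Targets of the coactivators YAP and TAZ were the 1 list called upward, with 19 of 28 genes rising, 5 falling and 4 not passing, or 20 and 5 adjusted over the list alone. The kinase gene NUAK2 rose by 1.84 log2 (SE 0.08), the transcription factor gene FOXF2 by 1.66 (SE 0.14), and DLC1 was at least 1.56-fold higher, while IGFBP3, an insulin-like growth factor binding protein, fell by 1.98 (SE 0.07). The median was 0.49 log2 (camera adjusted p = 0.0102, but adjusted p = 0.245 with an estimated correlation).

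Of mesenchymal markers 11 of 20 fell, 2 rose and 7 did not pass, or 11 and 3 adjusted over the list alone. LUM was at least 11.1-fold lower, S100A4 fell by 3.05 log2 (SE 0.09) and VIM, the intermediate filament vimentin, fell by 2.09 (SE 0.07; its other probe fell by 2.72), while TWIST1, a transcription factor of mesenchymal cells, rose by 2.40 (SE 0.08). The median was -0.37 log2, or -0.32 with genes seen in 1 group alone at their bound (camera adjusted p = 0.0120, but adjusted p = 0.245 with an estimated correlation). It was -0.11 without a filter on dim probes, -0.15 in the series matrix values and -0.58 with a stricter filter, and camera called the list under each, but not without any 1 of the 3 parental arrays (adjusted p = 0.0502 to 0.0651). There the filter of detection on 3 arrays takes out genes seen in parental cells alone, such as LUM. With detection on 2 arrays, chosen after seeing the data, the list passed (camera adjusted p = 0.0128 to 0.0263). Epithelial markers had a median of -0.20 log2 with 13 of 36 falling and 4 rising, or 14 and 4 adjusted over the list alone, and did not pass camera (adjusted p = 0.156).

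Lung lineage genes fell in 7 of 16 cases, rose in 3 and did not pass in 6, and the counts adjusted over the list alone were the same, 7 and 3. NKX2-1 and SFTA3 led the list, followed by the transcription factor gene SOX2 at least 3.77-fold lower (at least 1.64-fold on its other probe) and the aquaporin gene AQP3 at least 2.16-fold lower, bounds that were 2.02-fold and 1.44-fold without background correction. SOX2 lies on chromosome 3, as does MUC4, where 419 of 667 tested genes fell. The median was -0.29 log2, unchanged with its 4 bounded genes at their bound (camera adjusted p = 0.0151, but adjusted p = 0.245 with an estimated correlation). Mucin and secretory genes fell in 7 of 9 cases and rose in 1, also adjusted over the list alone. CEACAM6 was at least 12.8-fold lower and the tetraspanin gene TSPAN8 fell by 1.12 log2 (SE 0.09), while the trefoil factor gene TFF1 rose by 2.84 (SE 0.12). MUC4 fell on its brightest probe, from a mean log2 signal of 10.70 to 9.70, but its other probe, detected on all arrays, was called higher by 0.45 (limma adjusted p = 0.0134), and the mean of both did not pass (-0.28, limma adjusted p = 0.0607). The median was -0.53 log2 (camera adjusted p = 0.0151, but adjusted p = 0.572 with an estimated correlation). Without a filter on dim probes the medians shrank to -0.050 for the lung lineage and -0.090 for mucins, and neither list passed camera (adjusted p = 0.0840 and 0.109). In the series matrix values the medians were -0.076 and -0.34, and without background correction that of the lung lineage was -0.18, with both lists called. Without any 1 of the 3 parental arrays neither passed (adjusted p = 0.497 to 0.534 for the lung lineage and 0.0769 to 0.101 for mucins). There the filter of detection on 3 arrays takes out every gene seen in parental cells alone, so these losses do not show dependence on 1 array. With detection on 2 arrays, chosen after seeing the data, both lists passed (camera adjusted p = 0.0110 to 0.0128 and 0.0263 to 0.0341).

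**Figure D2:**
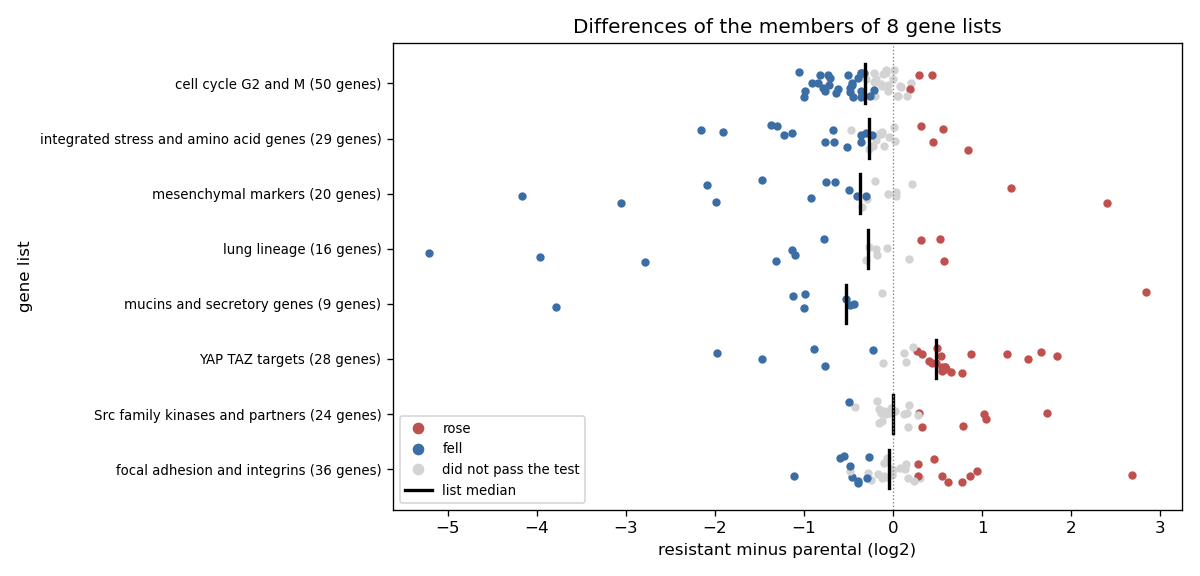
Log2 difference between resistant and parental cells for each tested gene of 8 lists, 1 point per gene coloured by its limma call, with the list median as a bar, and genes seen in 1 group alone at their fitted difference, not at their bound. Medians run from -0.53 in mucin and secretory genes to 0.49 in YAP and TAZ targets.

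Of the lists that mark other cell types none passed camera. Leukocyte markers had 4 of 10 genes rising and 3 falling (5 and 3 adjusted over the list alone, camera adjusted p = 0.716), and endothelial and stromal markers 2 of 7 rising and 3 falling (3 and 3 adjusted over the list alone, 0.716). Neuroendocrine and neuronal markers had 5 of 8 rising and 1 falling, with the same counts adjusted over the list alone, and a camera adjusted p of 0.105. Squamous markers had 3 of 9 rising and 1 falling, also with the same counts adjusted over the list alone (camera adjusted p = 0.394).

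Apart from YAP and TAZ targets, the other signalling lists did not pass camera either. Other receptor tyrosine kinases had 5 of 20 genes rising and 9 falling (6 and 9 adjusted over the list alone, camera adjusted p = 0.669), growth factor ligands 4 of 20 and 5 (4 and 7 adjusted over the list alone, 0.857), and genes that report MAPK output 9 of 29 and 7 (10 and 8 adjusted over the list alone, 0.857). Genes responsive to PI3K and FOXO had 2 of 20 rising and 7 falling (3 and 8 adjusted over the list alone, 0.153), TGF-beta responsive genes 6 of 20 and 3 (7 and 4 adjusted over the list alone, 0.583), Wnt targets 6 of 19 and 4 (6 and 5 adjusted over the list alone, 0.716), and Notch genes 4 of 15 and 3 (4 and 3 adjusted over the list alone, 0.731). Extracellular matrix genes had 8 of 25 rising and 9 falling (8 and 10 adjusted over the list alone, 0.731), and matrix proteases and their inhibitors 4 of 18 rising and 10 falling (4 and 11 adjusted over the list alone, 0.131) with a median of -0.41 log2.

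Immune and damage response genes moved both ways. Interferon stimulated genes had 14 of 41 rising and 12 falling, with the same counts adjusted over the list alone (camera adjusted p = 0.857), and antigen presentation genes 10 of 21 and 5 (12 and 6 adjusted over the list alone, 0.394). NF-kB and inflammatory genes had 12 of 31 rising and 10 falling, again the same adjusted over the list alone (0.948), and complement and coagulation genes 4 of 21 and 8 (4 and 9 adjusted over the list alone, 0.669). Targets of p53 had 11 of 30 rising and 7 falling (11 and 9 adjusted over the list alone, 0.857), the BCL2 family and cell death genes 10 of 28 and 7, the same adjusted over the list alone (0.948), and stem-like and drug tolerance markers 4 of 19 and 8 (5 and 9 adjusted over the list alone, 0.669).

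Apart from integrated stress and amino acid genes, metabolic and stress lists did not pass camera. Hypoxia and glycolysis genes had 12 of 32 rising and 3 falling (13 and 3 adjusted over the list alone, camera adjusted p = 0.131), and oxidative phosphorylation genes 2 of 40 rising and 7 falling (1 and 6 adjusted over the list alone, 0.422). Cholesterol synthesis genes had 5 of 20 rising and 4 falling (5 and 5 adjusted over the list alone, 0.948), fatty acid and lipid synthesis genes 9 of 25 and 9, the same adjusted over the list alone (0.857), and lysosome and autophagy genes 13 of 43 and 8 (13 and 9 adjusted over the list alone, 0.626). ER chaperones had 7 of 25 rising and 5 falling and heat shock chaperones 3 of 22 and 4, both the same adjusted over the list alone (0.949 and 0.948). NRF2 targets had 8 of 30 rising and 10 falling (10 and 10 adjusted over the list alone, 0.857), AHR targets 3 of 15 and 4 (3 and 5 adjusted over the list alone, 0.857), xenobiotic metabolism genes 9 of 26 and 9 (11 and 9 adjusted over the list alone, 0.857), and ABC transporters 5 of 12 and 6, the same adjusted over the list alone (0.870).

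Besides the Src and focal adhesion lists, 8 tested lists had a median and a mean of opposite signs. The median was above 0 and the mean below 0 for p53, interferon, NF-kB, ER chaperone, cholesterol, fatty acid and xenobiotic genes, and the reverse held for heat shock chaperones. Camera pointed downward with the mean for NF-kB and fatty acid genes, and with the median for the others. For BCL2 family genes camera pointed upward while median and mean were both below 0. The dovitinib target kinases, too few for camera, had a median of -0.071 log2 and a mean of 0.05.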

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

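Leaving out 1 array with the detection filter lowered to 2 arrays was chosen after seeing the data; the other alternatives were planned. Of the 65 named genes tested, 62 kept their direction and their side of the threshold under all alternatives that tested them, none of 1448 gene results reversed, and 14 were weaker (FGFR3, FGFR4 and MUC4). Most of these genes were named for large differences in the main fit of the same arrays, so their calls were likely to hold. FGFR3 and FGFR4 are among the few named whatever their result. Counts of at least 2-fold changes depended on the background: 269 higher and 299 lower without correction, and 308 and 344 with normexp at an offset of 50, against 580 and 583. The series matrix values, without normalization, gave 2081 lower probes and 220 at least 2-fold lower. An adjusted p under 0.01 left 2574 higher and 2409 lower probes. Lists called numbered 0 with an estimated correlation in camera (5 at an unadjusted p under 0.05), 32 with fry, which does not compare a list with other genes, and 3 to 7 without 1 array. Without parental replicate 1, 2 or 3 only 3 lists passed: the lung lineage (adjusted p = 0.497 to 0.534), mesenchymal (0.0502 to 0.0651) and mucin lists (0.0769 to 0.101) did not. With 2 parental arrays a gene seen in parental cells alone cannot be detected on 3 arrays, so 7 named genes left the test there, and 8 without a resistant array. With detection on 2 arrays 6 lists passed in all 6 settings and no named gene left, at an adjusted p of 0.00960 to 0.0132, 0.00715 to 0.0263 and 0.0263 to 0.0457 for these 3 lists. Over all alternatives run with camera the adjusted p ran from 2.35e-06 to 0.534 for the lung lineage, 0.00574 to 0.572 for mucins and 3.56e-07 to 0.171 for G2 and M genes. The estimated correlations of the called lists other than mucins lay below the preset 0.01, so a higher correlation did not end those calls. What ended those and the other lost calls was not tested, except for the lung lineage, mesenchymal and mucin calls lost without a parental array. These returned with detection on 2 arrays, a filter chosen after seeing the data. Whether replicate numbers pair the arrays stays open. Deviations of arrays with the same number correlated at 0.085, 0.16 and -0.010, against -0.16 to 0.076 for different numbers. Of the 6 arrays 4 correlated best with their own number. With the number as a replicate block 7677 probes changed, against 8133, and 6 lists passed. The slide as a block was not run, since no slide is given in the files. Signal over background limits genes near the detection limit, where folds are compressed or only bounded.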

Other observations

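The values per chromosome, the shuffles within chromosomes and the neighbours of NKX2-1, MYC and PVT1 were chosen only after the result was seen, and the gene list for the test of another cell line was recorded after 3 of its 14 genes (ERAP2, GSTM1 and GSTT1) had been seen.

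Changes differed in direction between chromosomes, with genes placed by assembly GRCh38.p14. On chromosome 20, 250 of 328 tested genes rose and 8 fell, with a median of 0.62 log2 (0.53 to 0.70 under 4 other normalizations). On chromosome 3, 419 of 667 fell and 38 rose, with a median of -0.44 (-0.45 to -0.36), and on chromosomes 13 and 18 the medians were -0.25 and -0.28, with 99 of 216 and 66 of 156 genes falling. SRC, at 0.79, stood close to the median of its chromosome, and PTPN1 at 1.05 and MYL9, SDCBP2, MAP1LC3A and EEF1A2 lie on chromosome 20 too. When each gene's chromosome median was taken off, the list medians were -0.37 for G2 and M genes, 0.45 for YAP and TAZ targets, -0.43 for the lung lineage, -0.37 for integrated stress genes, -0.41 for mesenchymal markers and -0.75 for mucins, all in the direction they had before. For the Src list the median moved from -0.0017 to 0.08. Of 11625 windows of 10 neighbouring genes, 868 held 7 or more genes called 1 way, 568 of them on chromosomes 3 and 20, against at most 82 in 1000 shuffles of the gene order over the genome and at most 744 in 1000 shuffles within chromosomes. Copy number was not measured.

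PVT1 rose by 4.96 log2 while, on the same arm of chromosome 8, WASHC5, LRATD2 and CYRIB fell (-3.26, -2.79 and -2.85). Between them NSMCE2, TRIB1 and MYC fell (-0.60, -0.63 and -0.59) and GSDMC rose by 1.48. MIR1204, within PVT1 and detected on 1 parental and 3 resistant arrays, rose by 5.06. Beside these genes SQLE fell by 2.57. Another normalization as the cause is argued against only weakly: over 4 others the smallest difference of the 4 genes was 2.72 log2. The bound set beforehand was a 2-fold difference, and the smallest in the main fit was 2.79 log2. The check could therefore hardly come out otherwise. Changes shared by neighbouring genes stay open here: 0 of 1000 shuffles of the gene order reached the windows counted over the genome, but chromosomes 3 and 20 hold 568 of the 868, and of 18 windows with at least 1 of the 4 genes 2 are among them. A probe artefact stays open: 100% of the other tested probes of the 4 genes went the gene's way, but the bound set for excluding it was met by a single probe, because only CYRIB has another tested one. The probe of MIR1204 gives a second reading within PVT1, but WASHC5 and LRATD2 have no second reading. A hypothesis is that rearrangement or copy number change along the arm may underlie the opposite changes, which RNA signals cannot test, and resistance itself stays open as a cause.

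NKX2-1 and SFTA3, which neighbour each other on chromosome 14, were lost from detection in resistant cells, and beside them PAX9 and MBIP fell (-1.25 and -0.70 log2) and SLC25A21 was at least 2.11-fold lower. Another normalization is argued against for 4 others, over which the highest list median was -0.18 (against -0.29, camera adjusted p = 0.0151, but adjusted p = 0.245 with an estimated correlation). In the unnormalized series matrix values, left out of that test, the list median was -0.076 and would miss the bound set beforehand. There the median of all tested probes lay 0.11 log2 above 0. Stromal cells in the parental cultures stay open, although the bound set for excluding them was met: 0 of 3 fibroblast collagens were at least 2-fold lower. In parental cells COL3A1 was not detected and COL1A2 lay only 0.23 log2 above the lowest detected signal, too low to show such a drop. COL1A1 lay 0.93 above it, was still detected on all 3 resistant arrays and fell by 0.50, short of 2-fold. It alone, near the detection limit where folds are compressed, does not exclude them. While such low collagens speak for few stromal cells, LUM was at least 11.1-fold lower, ACTA2 fell by 0.92 and COL1A1 fell by 0.50 (limma adjusted p = 6.27e-07, 0.000281 and 0.0416). Another cell line in place of the resistant cells stays open. Of 14 genes that common germline deletions or null alleles silence, 11 have a probe and 0 were detected on all resistant arrays and no parental one. Of the 11, 7 were detected on all arrays, 3 on none, and LRRC37A2 on 3 parental and 2 resistant arrays. These 11 genes are too few to exclude another cell line. The association with resistance, as a loss of lung lineage identity, is a hypothesis that no test here could separate from drift of the line in culture.

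Of G2 and M genes 27 of 50 fell, 3 rose and 20 did not pass, with a list median of -0.31 log2 (camera adjusted p = 5.85e-05, but adjusted p = 0.171 with an estimated correlation). A difference in normalization is argued against for 4 others, over which the highest median was -0.23. In the unnormalized series matrix values, left out of that test, it was -0.14 and would miss the bound set beforehand. There the median of all tested probes lay 0.11 log2 above 0. Signal level is argued against as well, since the median stood at percentile 0 among 10000 lists matched on mean signal. G1/S and S phase genes went the other way without passing camera, with 15 of 41 rising, 6 falling and a median of 0.19. Growth rate and culture density were not measured, and resistance itself stays open as a cause.

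With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and for each count below 1 split, the real one, gave a value as large. The real split gave 8133 changed probes in limma and the highest other split 0 (10006 and 660 at an unadjusted p under 0.05). At least 2-fold changed were 1163 probes, with 0 in the highest other split (1167 and 11 at an unadjusted p under 0.05). Camera called 6 lists, and the highest other split 4. Every other split puts arrays of both groups together, so the real difference adds to the spread within its groups and partly remains between them. The counts of the other splits therefore cannot show what no difference would give.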
